A study of Mus musculus with 8 samples.

How the data were processed

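Total RNA (100 ng, purified with RNeasy Micro) from hand-dissected E16 V/SVZ and CP was amplified and labelled with Cy3 by the Low Input Quick Amp protocol and hybridised to 1-colour Agilent arrays, per the labels' protocols. Per the file headers, each array was read with Agilent Feature Extraction 10.7.1.1, which made the deposited intensity values used here: a processed signal per spot, background-subtracted and detrended within the array, and the median signals of spot and local background. No normalization between arrays is given in the sources used here. The authors also deposited a table of log2 values for 17185 rows, of which 17163 are gene probes. Its values have a median of 0 over the 8 columns in 99.8% of rows (tolerance 1e-05). Its log2 base and centring were inferred by setting each column against the scanner arrays, while its filter and its scaling between arrays stay unknown. Column medians ran from -0.03 to 0.02. Each column followed the same-numbered array of the other tissue and not the array it is named for, so the table was used only as an alternative, with its direction turned to that of the scanner files. No column of per-sample values was left unmapped (0 columns).

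Groups and replicate numbers (4 per tissue) came from the sample titles. Spots of a probe were averaged on the log2 scale, leaving out control spots and spots marked as non-uniform or population outliers (142 to 258 per array). No gene spot was saturated. The main values were log2 of the processed signal minus the 75th percentile of each array. A probe was tested where it was well above background on all 4 arrays of at least 1 tissue and had a value on at least 3 arrays of each, which left 23860 of 39429 gene probes. The files carry accessions and no gene symbols. Unversioned accessions were matched to symbols through a RefSeq table of assembly GRCm38.p6, which named 26761 probes and left 12668 under their own identifiers. The array headers name build mm9, so no coordinates are given. A gene was represented by its tested probe with the highest mean signal, giving 19232 genes, of which 13831 have a symbol. Differences are V/SVZ minus CP, fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Where the probe of a gene was not well above background on any array of a tissue, the fold is given as "at least". It sets the bright tissue's mean against the mean of, per array, the higher of the dim probe's value and the lowest signal among probes well above background.

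The 35 gene lists were written before the data were examined, together with the design, the alternatives and the rule for named genes. Of 907 listed genes, 815 were tested. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether the genes of a list move on balance one way. Named genes were the 10 largest differences in each direction among called genes that do not overlap between tissues and are well above background on all 8 arrays, and the 3 largest bounds in each direction. From each neuronal, progenitor or metabolic list they were the 3 called genes with the largest absolute difference that are well above background on all 8 arrays, and the called gene furthest against the majority. Where fewer than 2 genes of such a list were called, its 2 brightest genes were to be named. From each list of another cell type or state they were the called gene with the largest difference, or the brightest gene where none was called, and the markers Pax6, Sox2, Eomes, Bcl11b and Tbr1 were named in any case, while 1 further marker of this rule is not reported here. Clone, predicted and accession names were passed over among the largest differences and bounds. Members named where a count was 5 or fewer, and genes singled out for probes that disagree, were chosen after their values were seen.

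The procedure was tested on simulated data of 23808 probes with known changes. It called 65.9% of log2 differences of 0.5, 80.3% of 1 and 95.2% of 2, and 2.96% of its calls were false. It called 0 of 150 unchanged lists and 25 of 25 raised lists. The simulated noise was independent between probes, only a small share of probes was changed, and list members were drawn at random. In the real data most genes were called and genes of a list can vary together, so these rates do not carry over to the real data. Alternatives covered the scaling, background correction, filter, choice of probe, replicate block, variance model, array weights, the authors' deposited table and each array left out. Scaling on the spike-in RNAs, the deposited table with its columns as named, and leaving out genes whose probes disagree were added after seeing the data. The files hold no mean signal column, so normexp (offset 50) was run on the median signals. The number of arrays limits the precision.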

Results

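RNA was profiled from the wall of the mouse neocortex (ICR strain) at embryonic day 16, a stage at which neurons were still being produced. Tissue had been dissected by hand into the ventricular and subventricular zones (V/SVZ), which line the ventricle and hold the dividing progenitors, and the cortical plate (CP), where postmitotic neurons settle. Each tissue was represented by 4 samples, each on its own 1-colour array, and the comparison asks which transcripts separate the germinal zones from the plate. Between 58.4% and 62.9% of the 39429 gene probes were well above background on each array, and the 75th percentile of the signal lay between 2113 and 2566 intensity units. Correlations across genes, which are not independent replicates, ran from 0.992 to 0.995 among the V/SVZ arrays, from 0.996 to 0.997 among the CP arrays, and from 0.880 to 0.897 between the tissues. Nothing in the labels says that the samples of a tissue came from separate animals, so p-values measure the spread between these samples, which may be technical. All V/SVZ arrays were on slide 1 and all CP arrays on slide 2, so the design does not separate slide from tissue.

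The 2 tissues differed across most of the transcriptome. V/SVZ was marked by transcription factors of progenitors: Eomes, a factor of intermediate progenitors, was 336-fold higher there (log2 difference 8.39 ± 0.18 SE, n = 4 per tissue, limma adjusted p = 3.28e-09), and Pax6, a factor of radial glia, was at least 105-fold higher. After normexp background correction Pax6 was 38.6-fold higher, and with the mean of its probes 44.5-fold, both below that bound. CP was marked by genes of differentiating neurons: Camk2b, a subunit of the neuronal calcium/calmodulin-dependent kinase, had a log2 difference of -7.35 ± 0.08 SE, which is 164-fold higher in CP. Of 19232 genes tested, 6727 were higher in V/SVZ and 8571 higher in CP, together 79.5% of those tested. At 2-fold or more, 2637 genes were higher in V/SVZ and 3180 higher in CP, and at 8-fold or more the counts were 688 and 618. Among genes with a symbol, 2193 were at least 2-fold higher in V/SVZ and 2170 in CP. The larger CP count at 2-fold thus came from the 5401 entries without a symbol. Of the called genes, 517 higher in V/SVZ had no probe well above background on any CP array, and 313 higher in CP none on any V/SVZ array. Of the genes at 2-fold or more, 155 higher in V/SVZ and 26 higher in CP reach 2-fold only through a dim value, since their bound is lower. The median difference of all genes was -0.09 on the log2 scale. Spike-in RNAs added at labelling differed by up to 0.16 on this scale between the slides, and 713 of the called genes, 4.66% of the calls, differed by no more than that. The dimmest of these spike-ins had an unscaled mean log2 signal of 8.63 in V/SVZ and 8.33 in CP. A slide difference at dimmer signals was therefore not covered, and the share of calls within it is not known.

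**Figure D1:**
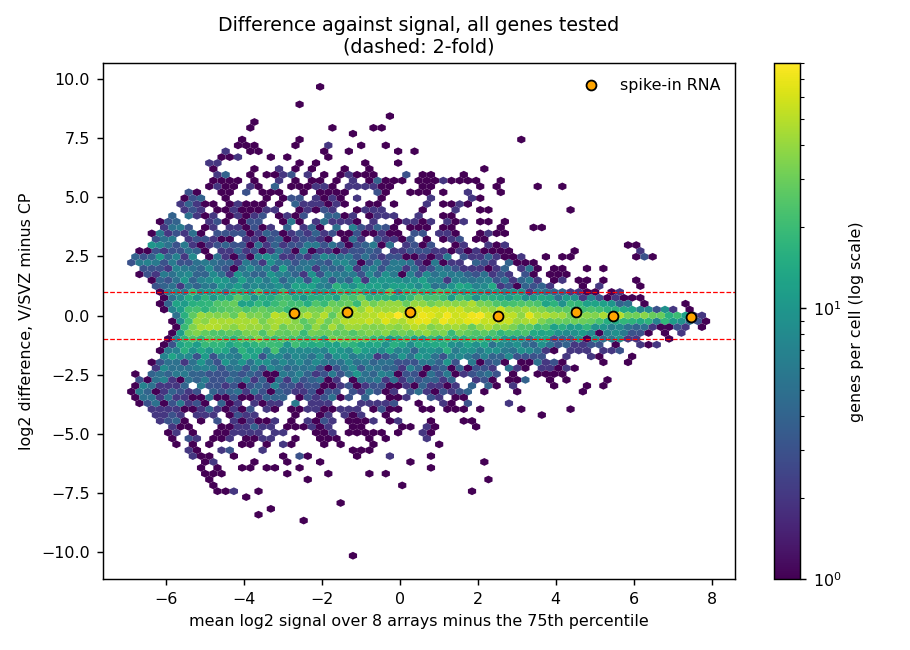
Each hexagon gives the number of genes (colour, log scale) at a mean log2 signal over the 8 arrays (horizontal axis, relative to the 75th percentile) and a log2 difference, V/SVZ minus CP (vertical axis). Dashed lines mark 2-fold, beyond which 2637 called genes lie above and 3180 below, and the 7 spike-in RNAs (orange) lie within 0.16 of 0.

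Among genes well above background on all 8 arrays, the largest differences towards V/SVZ after Eomes were those of Gli3, a transcription factor of hedgehog signalling (242-fold), Mlc1 (225-fold), the glycolytic enzyme gene Aldoc (160-fold), the noncoding RNA Snhg18 (152-fold), and Nr2e1, a nuclear receptor of neural stem cells (146-fold). They were followed by Aldh1l1 (130-fold), the collagen gene Col2a1 (123-fold), Sox3, a factor of neural progenitors (114-fold), and Vit (99.0-fold). Of the genes not well above background in CP, Tfap2c was at least 371-fold and Loxl1, a lysyl oxidase family member, at least 115-fold higher in V/SVZ. Towards CP, Camk2b was followed by the neurotensin receptor gene Ntsr1 (152-fold higher in CP, 69.4-fold with the mean of its probes), the dynein intermediate chain gene Dync1i1 (131-fold), Caln1 (106-fold), the adenylyl cyclase gene Adcy1 (97.2-fold), Sla (91.6-fold), the neuronal surface glycoprotein gene Thy1 (82.5-fold), Bend6 (76.5-fold), Camkv (68.7-fold) and Tmtc1 (67.4-fold). Of the genes not well above background in V/SVZ, the melanocortin receptor gene Mc4r was at least 114-fold, Ccbe1 at least 110-fold and Hs3st2 at least 74.1-fold higher in CP. These folds and bounds depend on the background correction of the scanner software, and some also on the choice of probe. After normexp, Eomes was 191-fold, Gli3 126-fold, Mlc1 113-fold, Snhg18 77.2-fold, Nr2e1 76.9-fold, Col2a1 57.0-fold and Vit 43.2-fold higher in V/SVZ, and Caln1 62.8-fold, Tmtc1 44.5-fold and Thy1 35.8-fold higher in CP. Also after normexp, all 14 genes named with a bound fell below that bound. Tfap2c was then 155-fold and Loxl1 39.4-fold higher in V/SVZ, and Mc4r 49.8-fold, Ccbe1 40.9-fold and Hs3st2 34.2-fold higher in CP. In each of these genes the 4 arrays of one tissue all lay above the 4 of the other, which their choice required except for the genes with a bound. The same held in 14329 of the 15298 called genes. Adjusted p ranged from 3.39e-11 for Camkv to 9.32e-07 for Hs3st2.

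Progenitor genes were higher in V/SVZ nearly as a block. Of 30 radial glia genes tested, 28 were higher in V/SVZ, with a list median of 4.29 on the log2 scale (4.12 with genes at their detection bound). Beyond Aldoc, the examples were Id4, an inhibitor of basic helix-loop-helix factors (54.8-fold), and the fatty acid binding protein gene Fabp7 (41.7-fold). Sox2, a factor of neural stem cells, had a log2 difference of 3.32 ± 0.08 SE. Ptprz1 was the only radial glia gene higher in CP, by 1.44-fold, and Notch1 was not called (log2 difference -0.55 ± 0.31 SE, adjusted p = 0.133). Of 22 intermediate progenitor genes, 19 were higher in V/SVZ, among them Eomes, Mfap4 (58.6-fold) and the proneural factor gene Neurog2 (47.8-fold). The 3 higher in CP were Chst2 (3.50-fold), Nhlh1 and Mgat5b, with log2 differences of -0.46 for Nhlh1 and -0.29 for Mgat5b. A second Nhlh1 probe was called the other way, at 3.22. Both lists were called towards V/SVZ by camera with its preset correlation, at adjusted p = 5.65e-12 for radial glia and adjusted p = 1.34e-06 for intermediate progenitors. With an estimated correlation the radial glia list kept its call (adjusted p = 0.0423), and the intermediate progenitor list lost it (adjusted p = 0.0657 with an estimated correlation).

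The cell cycle genes were higher in V/SVZ with almost no exception. All 46 mitosis genes tested were higher there, with a list median of 5.09 (4.32 after normexp). The cyclin gene Ccnb1 was 57.4-fold, the spindle protein gene Nusap1 52.7-fold and the topoisomerase gene Top2a 52.2-fold higher. Of 40 DNA replication genes, 38 were higher in V/SVZ, including the thymidine kinase gene Tk1 (49.9-fold), the replication factor gene Mcm10 (42.2-fold, 23.7-fold after normexp) and Uhrf1, which acts in maintenance of DNA methylation (31.1-fold). Gins3 and Prim2 were not called, with log2 differences of 0.03 and 0.52. Of 35 DNA repair genes, 33 were higher in V/SVZ, such as Exo1 (38.0-fold, 20.8-fold after normexp), Fanci (33.1-fold, 15.7-fold after normexp) and Fanca (21.4-fold). Lig4, a ligase of end joining, was 1.41-fold higher in CP, and Atm was not called (-0.10). Camera called the 3 lists at adjusted p = 5.50e-21 for mitosis, adjusted p = 1.43e-15 for DNA replication and adjusted p = 3.28e-10 for DNA repair. None of these calls held when the correlation was estimated: mitosis had adjusted p = 0.0875 with an estimated correlation, DNA replication adjusted p = 0.123 with an estimated correlation, and DNA repair adjusted p = 0.0524 with an estimated correlation.

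**Figure D2:**
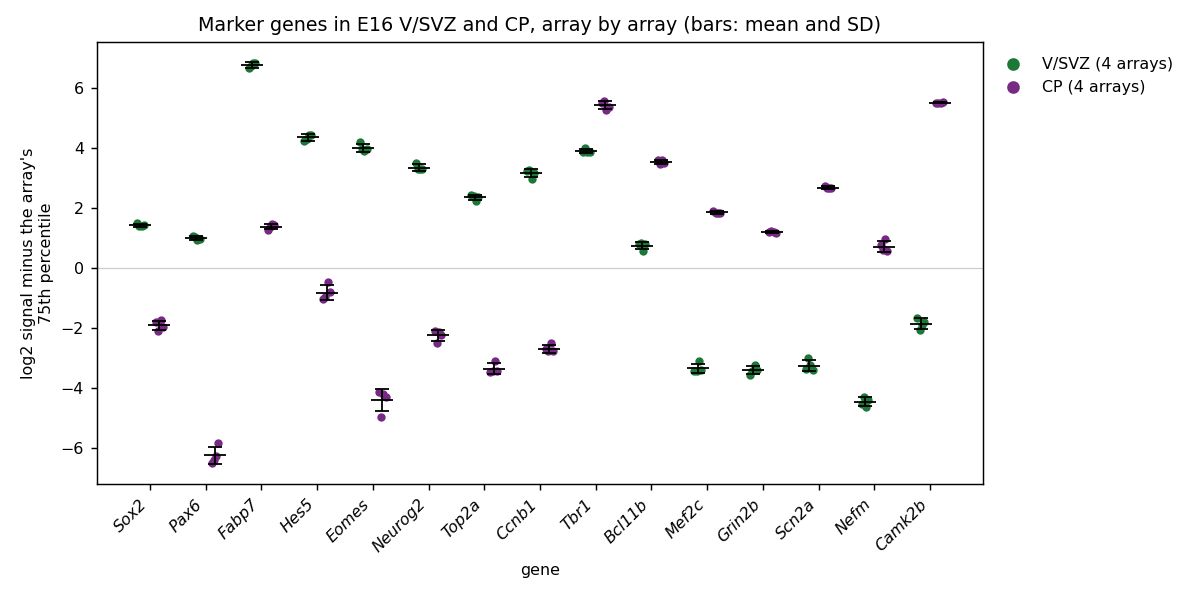
Points give the log2 signal of each array minus its 75th percentile (vertical axis) for 15 named genes (horizontal axis), in green for the 4 V/SVZ arrays and in purple for the 4 CP arrays, with bars for the mean and SD. In each gene the arrays of the 2 tissues do not overlap, and the Pax6 values in CP are not well above background.

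Signalling genes of the germinal zones went the same way in most cases. In the Notch pathway, 18 of 27 genes were higher in V/SVZ and 7 higher in CP. Examples were the receptor gene Notch2 (52.7-fold, 31.9-fold after normexp and 21.7-fold with the mean of its probes), the effector gene Hes5 (35.9-fold) and Mfng, a glycosyltransferase that modifies Notch (23.1-fold), while Dtx4 was 5.88-fold higher in CP. Notch1 and Maml2 (log2 difference 0.10) were not called. Among 32 genes of Wnt, Fgf and hedgehog signalling, 26 were higher in V/SVZ, among them Gli3 and the Wnt receptor genes Fzd2 (19.6-fold) and Fzd8 (17.5-fold). The 5 higher in CP were Dusp6, a phosphatase that restrains Erk (6.58-fold), Wnt7b (-1.55), Spry1 (-1.47), Fzd10 (-0.76) and Fzd9 (-0.63), the last 4 as log2 differences. Ptch1 was not called (0.09). Camera gave adjusted p = 0.00244 for the Notch pathway, which was adjusted p = 0.0657 with an estimated correlation, and adjusted p = 1.14e-05 for the Wnt, Fgf and hedgehog list, which kept its call at adjusted p = 0.0423.

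In CP, the machinery of differentiated neurons was higher. All 36 neuronal cytoskeleton genes tested were higher in CP, with a list median of -1.75, including Dync1i1, Thy1 and the neurofilament gene Nefm (36.0-fold, 21.7-fold after normexp). Of 47 synaptic transmission genes, 43 were higher in CP. Examples were Camk2b, the glutamate receptor gene Grin2b (24.5-fold) and the GABA receptor gene Gabra3 (15.8-fold). The 3 synaptic genes higher in V/SVZ were Slc17a6, a vesicular glutamate transporter (3.66-fold), Syt11 (log2 difference 0.69) and Camk2a (0.34). A second Camk2a probe was called the other way, at -0.33, and Syn2 was not called (-0.07). Of 35 voltage-gated ion channel genes, 30 were higher in CP, such as the sodium channel gene Scn2a (60.8-fold, 27.8-fold with the mean of its probes), the potassium channel gene Kcnma1 (40.1-fold, 23.1-fold after normexp) and the calcium channel gene Cacna1g (12.5-fold). Kcnd3 was 1.20-fold higher in V/SVZ. Kcnt2, Kcnq3, Kcnh7 and Kcnn2 were not called, at log2 differences of -0.77, -0.52, 0.04 and 0.04. These 3 lists were called towards CP, at adjusted p = 7.42e-12 for the cytoskeleton, adjusted p = 8.77e-10 for synaptic transmission and adjusted p = 4.50e-07 for ion channels. All 3 calls held with an estimated correlation, each at adjusted p = 0.0423.

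Markers of deep and upper layers were higher in CP in most cases, with exceptions in each list, and subplate markers went both ways. Of 24 deep-layer neuron genes, 20 were higher in CP, among them Nfe2l3 (55.1-fold, 25.5-fold after normexp), Ldb2 (25.4-fold) and Tshz3 (14.2-fold). Bcl11b, a factor of subcerebral projection neurons, was 6.91-fold higher in CP (log2 difference -2.79 ± 0.07 SE), and Tbr1, a factor of layer 6 neurons, 2.89-fold (-1.53 ± 0.08 SE). Etv1 and Pcp4 were higher in V/SVZ, Etv1 by 2.42-fold and Pcp4 with a log2 difference of 1.22, and Tshz2 (-0.25) and Grik2 (0.11) were not called. Of 20 upper-layer neuron genes, 13 were higher in CP, among them Inhba (50.6-fold), Mef2c (36.5-fold) and Kitl (13.4-fold). The 6 higher in V/SVZ included the netrin receptor gene Unc5d, by at least 3.77-fold (2.17-fold after normexp), and Cux2 was not called (0.11). Subplate genes divided into 8 higher in CP, with Mef2c and Kcnab1 (17.2-fold) as examples, and 7 higher in V/SVZ, with the matrix protein gene Ccn2 at 10.8-fold. Nxph4 (0.06) and Pls3 (0.19) were not called. Camera called the deep-layer list at adjusted p = 3.20e-05, and the call was lost at adjusted p = 0.0524 with an estimated correlation. The upper-layer list (adjusted p = 0.240) and the subplate list (adjusted p = 0.885) were not called.

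Cajal-Retzius cell genes were nearly all higher in CP, while the other neuronal groups were mixed. Of 13 Cajal-Retzius cell genes, 12 were higher in CP, including the calcium channel subunit gene Cacna2d2 (13.5-fold), Nhlh2 (9.96-fold) and Trp73, whose log2 difference was -0.74, and -3.86 with the mean of its probes. The exception, Ebf1, was 1.21-fold higher in V/SVZ, but its value was -0.05 on the log2 scale after normexp background correction. Other lists also hold 7 of the 13 genes, and the remaining 6 were all higher in CP, with a median of -2.28. Camera called the Cajal-Retzius list at adjusted p = 0.00418, which was adjusted p = 0.250 with an estimated correlation. The call was also lost among genes well above background on all 8 arrays (adjusted p = 0.141). Of 30 neuronal differentiation transcription factor genes, 22 were higher in CP, such as Nhlh2 and Csrnp3 (5.65-fold), and 7 higher in V/SVZ, with the proneural factor gene Neurod1 at 7.76-fold. Rbfox3 was not called (-0.12). Its list was called at adjusted p = 0.0115, which was adjusted p = 0.0657 with an estimated correlation. Among 47 axon guidance and cell adhesion genes, 32 were higher in CP, such as Ephb1 (28.9-fold) and Cntn1 (27.8-fold), and 13 higher in V/SVZ, where the semaphorin gene Sema5a was 58.5-fold higher. Sema4d (0.01) and Sema3a (0.04) were not called, and neither was the list (adjusted p = 0.0539), which was called in 5 other settings, among them median scaling (adjusted p = 0.0317). Among 34 neuronal migration genes, 20 were higher in CP, as was Dab1, the adaptor of reelin signalling (8.43-fold, with a log2 difference of -2.20 with the mean of its probes), and 11 higher in V/SVZ, including Nde1 (36.8-fold) and Rnd2 (9.08-fold). Cxcr4 (-0.19), Kif2a (-0.17) and Astn2 (-0.04) were not called, and the list was not called (adjusted p = 0.301).

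**Figure D3:**
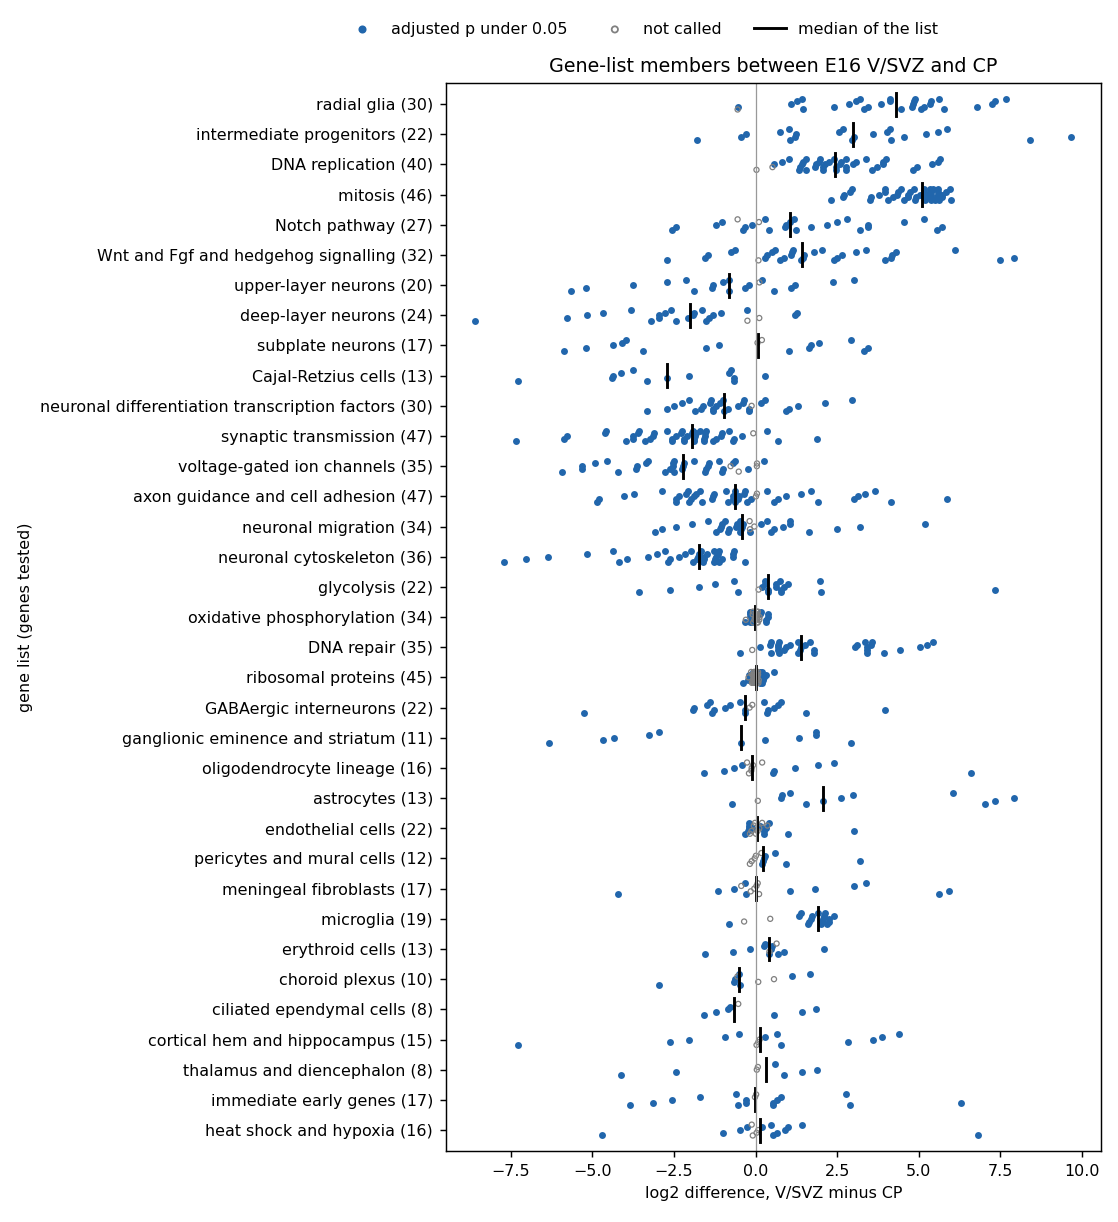
Each point is the log2 difference of a gene, V/SVZ minus CP (horizontal axis), in 1 of 35 gene lists (vertical axis, number of genes tested in brackets), filled where the gene was called, with a black bar at the list median. The mitosis list has its median at 5.09 and the neuronal cytoskeleton list at -1.75, while the ribosomal protein genes gather within 0.56 of 0.

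Genes listed as markers of microglia and of astrocytes also differed between the tissues, though these values do not tell which cells expressed them. Of 19 microglia genes tested, 16 were higher in V/SVZ, with a list median of 1.91, and P2ry12, a purinergic receptor of microglia, was 5.22-fold higher. Itgam was higher in CP (-0.81, with a second probe at 0.21), and Ptprc (-0.35) and Aif1 (0.45) were not called. The list was called at adjusted p = 0.000162, which was adjusted p = 0.411 with an estimated correlation (estimate 0.509). Over the microglia genes, array V/SVZ 1 had a median deviation of -0.41 and V/SVZ 4 of 0.41 from the other V/SVZ arrays. Of 13 astrocyte genes, 11 were higher in V/SVZ, where Gli3 and Aldoc, which other lists above also hold, had the largest differences. Without these 2, 9 of 11 were higher, with a median of 1.53. Sparcl1 was higher in CP (-0.71) and Gfap was not called (0.07). The astrocyte list was called at adjusted p = 0.000275, which was adjusted p = 0.250 with an estimated correlation.

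Counts of called members, adjusted over the list alone, were the same as over all genes tested in 29 of the 35 lists, including each neuronal and progenitor list given above. Camera with its preset correlation called 15 of the 35 lists, 9 towards V/SVZ and 6 towards CP. With an estimated correlation 5 held: radial glia, the Wnt, Fgf and hedgehog list, synaptic transmission, ion channels and the neuronal cytoskeleton. Different probes of 1 gene were called in opposite directions in 318 of the 3865 genes with several tested probes. In 847 of these 3865 genes some probes were called and others were not, so the call can depend on the probe used.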

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

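The tests of the deposited table were chosen after its mismatch had been seen. The counts over all splits and the spike-in test were chosen before, but the grouping of splits by their mix of tissues was not among them. The 8 columns of the authors' deposited table run against the arrays they are named for: across gene probes, the highest correlation of a column with its own array was -0.95. A sign turned in the table is argued against, because with the sign turned at least 1 column followed another array more closely than its own (smallest margin in r -0.0105). Scanner files exchanged between the tissues are also argued against, since 0 of 5 list medians were turned: radial glia, DNA replication and mitosis genes lay above 0 and synaptic and cytoskeleton genes below. An exchange of the tissues' column names is the only tested explanation that stays open, and may be the source. Every column followed the same-numbered array of the other tissue at r of 0.9987 to 0.9989, more closely than any other array (smallest margin in r 0.0217). No biological explanation was tested for this pattern.

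Slide and tissue are one split here, so part of each difference could come from labelling, hybridisation or scanning. Spike-in RNAs, which are added in equal amounts, differed from their median shift by at most 0.149 on the log2 scale (7 of 10 well above background on all 8 arrays). For signals as bright as these, that argues against such a step as the cause of differences of 2-fold or more. The dimmest of the 7 had an unscaled mean log2 signal of 8.63 in V/SVZ and 8.33 in CP, so dimmer signals were not covered. After scaling, 3 of the 7 were called, so small differences cannot be told apart from the slide. Negative controls had a net signal of 42.5 to 44.7 on the V/SVZ slide and 60.1 to 72.8 on the CP slide. The spike-ins do not see the dissection or the RNA extraction, which stay open, and the tissue difference that the design names stays open as well. Of the 35 splits of the 8 arrays into 4 and 4, only the real 1 reached 15298 called genes, or 5817 called at 2-fold or more, and the highest of the other splits called 1 gene in each case, which argues against chance for both counts, though 1 of 35 is the smallest share these splits can give. For the 15 called lists the count over all splits leaves chance open: 14 of the 35 splits called as many, up to 19. That count cannot decide the question, because splits that exchange 1 array of each tissue keep part of the tissue contrast. Those 16 splits called 14 to 19 lists. The 18 splits that mix the tissues evenly called at most 4, but they cannot decide the question either. In them the tissue difference cancels between the groups and adds to the spread within each, which holds the count down. The count of lists was thus not specific to the full split, and chance stays open for it.

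Single arrays stood apart from the other 3 of their tissue in 12 of 212 groups of 4 values, where 1 in 20 would by chance. The deviations, on the log2 scale from the mean of the other 3 arrays, were as follows. In array CP 3 they were 0.63 for Sox3, 0.35 for Tk1, 0.46 for Mcm10 and 0.35 for Top2a, all higher in V/SVZ. In V/SVZ 3 they were -0.23 for Uhrf1, 0.31 for Mef2c, -0.13 for Ndufa5 and 0.49 for Klf1. The remaining deviations were 0.0324 for Vit in V/SVZ 4, 0.20 for Neurog2 in V/SVZ 1, 0.14 for Tbr1 in V/SVZ 2 and -0.0343 for Eno2 in CP 1. Over whole lists, the median deviation of CP 3 was 0.12 for radial glia genes and 0.16 for mitosis genes, and that of V/SVZ 3 was -0.13 for mitosis genes.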

How the results depend on the processing

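Spike-in scaling, the deposited table with its columns as named, and leaving out genes whose probes disagree were tested only after the data were seen. Apart from the table with its columns as named and the other set tests, 2011 of 2020 values of named genes kept their direction and call, and 673 of 693 list values did. Most named genes were chosen for large called differences in the main setting, and the settings share the same arrays. These values are therefore not independent checks, and a high share was likely beforehand. Sizes moved more: 34 named genes differed by over 1.5 times after normexp, all towards 0, as did the medians of 5 lists (mitosis 5.09 to 4.32, intermediate progenitors 2.98 to 1.96, astrocytes 2.07 to 1.34, ion channels -2.23 to -1.48, Cajal-Retzius cells -2.71 to -1.37). With the mean of probes 10 did, among them Pax6 (5.48), Ccbe1 (-5.56), Ntsr1 (-6.12), Scn2a (-4.80), Notch2 (4.44), Dab1 (-2.20) and Pfkp (-2.15). Counts of all called genes and lists moved by over 1.5 times only with the authors' deposited table and with other set tests. With its direction taken from the scanner files, the table gave 1715 genes at least 2-fold higher in V/SVZ and 1707 in CP, from 14025 genes tested, and 11166 of its 11637 calls were shared with the main calls in direction. With its columns as named, 5466 genes were higher in CP, 1707 at least 2-fold higher in V/SVZ and 1715 in CP, and Eomes (-9.00), Pax6 (-7.24), Sox2 (-3.33), Bcl11b (2.78) and Tbr1 (1.52) were reversed by construction. Camera with an estimated correlation called 5 lists and fry 28. Ebf1 was reversed after normexp (-0.0533) and kept its direction without its call in 7 other settings, and Rpl22 was reversed with the mean of its probes (-0.15), since its 2 probes were called in opposite directions. Lists not called in the main setting were reversed without a filter (neuronal migration 0.0282, ciliated ependymal cells 0.0560), on genes well above background on all 8 arrays (choroid plexus 0.20, thalamus 0.23, immediate early genes -0.0842, heat shock and hypoxia -0.0265), with the mean of probes (thalamus 0.17) and with the authors' table (oxidative phosphorylation -0.0200, erythroid cells -0.0424); the cause was not tested. Leaving out 1 array gave 6451 to 6810 genes higher in V/SVZ, 8172 to 8590 higher in CP, 2626 to 2663 and 3039 to 3380 at 2-fold or more, and 15 to 17 lists. The share of calls towards V/SVZ was 44.0% in the main setting, 49.2% with median scaling, 39.6% with spike-in scaling and 35.5% without a filter on dim probes. Same-numbered arrays deviated together with r of 0.339, 0.308, 0.0980 and 0.204 for numbers 1 to 4. For numbers 1, 2 and 4 this was above the highest r with another number (-0.0738, 0.0353 and 0.160). An array numbered 3 deviated more closely with one of another number (0.206). The number is also the position of the array on its slide, so pairs and position cannot be told apart. The labels do not name pairs, and the main fit took none. The replicate block gave 6757 and 8620 genes, 2641 and 3178 at 2-fold or more, and 15 lists. The slide as a block was not run, since each slide holds 1 tissue. Genes not well above background in a tissue have only a bound there, and these bounds hold only for the main background correction and the probe used. After normexp, all 14 genes named with a bound fell below that bound. With the mean of probes, Pax6 was 44.5-fold and Loxl1 104-fold higher in V/SVZ and Ccbe1 47.2-fold higher in CP, each below its bound.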

Other observations

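The tests of probe pairs below were chosen before their results were seen, but the set of pairs was widened afterwards to genes without a symbol. Metabolic and housekeeping genes divided in their own ways. Of 22 glycolysis genes, 15 were higher in V/SVZ (16 adjusted over the list alone), with Aldoc in front, and 6 higher in CP, including the phosphofructokinase gene Pfkp (11.8-fold, 4.43-fold with the mean of its probes) and the neuronal enolase gene Eno2 (6.13-fold). Gapdh was not called (0.09), and the list was not called (adjusted p = 0.0640), though it was in 4 other settings, with adjusted p from 0.00360 without a filter on dim probes to 0.0465 with spike-in scaling. In oxidative phosphorylation, 6 of 34 genes were higher in V/SVZ and 12 in CP (6 and 11 adjusted over the list alone), all by less than 2-fold, with Sdha at 0.37, Atp5j at 0.37 and Ndufa5 at 0.33. These counts moved with the scaling, to 6 and 1 with median scaling, 13 and 8 with quantile normalization and 4 and 14 with spike-in scaling. Of 45 ribosomal protein genes, 13 were higher in V/SVZ and 6 in CP (10 and 3 adjusted over the list alone), none by 2-fold in the probe used. Examples were Rpl22 (0.56, with a second probe at -0.86), Rpl28 (0.31) and Rps7 (-0.40). Other ribosomal protein genes also had probes called both ways, such as Rps15a (-2.43 and 0.15) and Rpl6 (-0.78 and 0.12). The counts of ribosomal protein genes were 11 and 1 with median scaling, 19 and 2 with quantile normalization and 5 and 7 with spike-in scaling. Neither list was called (adjusted p = 0.874 and adjusted p = 0.492).

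Genes of other tissues and cell types near the dorsal cortex were mostly mixed, and none of the following 13 lists was called (adjusted p from 0.153 to 0.874). GABAergic interneuron genes were higher in V/SVZ in 8 of 22 cases and in CP in 12, with the neuropeptide gene Npy 38.0-fold higher in CP. Ganglionic eminence and striatum genes divided into 5 and 6 of 11, with Drd1 at least 24.6-fold higher in CP (log2 difference -3.58 after normexp). Oligodendrocyte lineage genes divided into 6 and 4 of 16, with Sox8 at least 27.1-fold higher in V/SVZ (10.9-fold after normexp). Endothelial genes divided into 7 and 6 of 22 (6 and 4 adjusted over the list alone, 7 and 1 with median scaling, 5 and 8 with spike-in scaling), with Slco1c1 8.05-fold higher in V/SVZ. Pericyte genes were higher in V/SVZ in 7 of 12 cases (6 adjusted over the list alone) and in CP in 0, with Notch3 9.11-fold higher, and that list passed without a filter on dim probes (adjusted p = 0.0203). Meningeal genes divided into 6 and 5 of 17 (6 and 4 adjusted over the list alone, 6 and 3 with median scaling), with Ogn at least 18.6-fold higher in V/SVZ (8.42-fold after normexp). Erythroid genes divided into 8 and 3 of 13, with Klf1 at least 1.93-fold higher in V/SVZ (1.31-fold after normexp). Choroid plexus genes divided into 2 and 5 of 10, with Sostdc1 higher in CP (log2 difference -2.96, and -1.49 after normexp, well above background on 2 V/SVZ arrays). Ependymal genes divided into 3 and 4 of 8, with Rsph1 higher in V/SVZ (1.84, and 0.65 after normexp, well above background on 1 CP array). Genes of the cortical hem and hippocampus divided into 7 and 5 of 15, with Rspo2 at least 33.5-fold higher in CP (19.8-fold after normexp). Genes of the thalamus divided into 4 and 2 of 8, with Calb2 at least 3.92-fold higher in CP (3.36-fold after normexp). Immediate early genes divided into 7 and 8 of 17, with Ccn1 higher in V/SVZ (log2 difference 6.29, and 4.83 after normexp, well above background on 2 CP arrays), and heat shock and hypoxia genes into 8 and 4 of 16, with Egln3 at least 72.1-fold higher in V/SVZ (28.8-fold after normexp). The median, the mean and the test differed in sign in 5 lists, none of them called: subplate, oxidative phosphorylation, oligodendrocyte lineage, thalamus and immediate early genes.

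Probes of 1 gene called in opposite directions numbered 419 of 3957 pairs, in 318 genes. In 90.2% of these opposite pairs both probes were well above background on all 8 arrays. That share alone says little, since 3359 of all 3957 pairs were as bright. Limiting the pairs to these bright ones did not lower the opposite share (11.3%, against 10.6% of all pairs). This argues against dim probes as the main source. Small differences around 0 stay open, as in only 4.30% of the opposite pairs did both probes differ by 2-fold or more. Probes of different transcripts may also contribute: opposite pairs matched different RefSeq transcripts in 23.4% of cases against 13.6% of pairs called the same way (odds ratio 1.94, 95% interval 1.5 to 2.49, Fisher's exact test p = 3.81e-07, and 1.91 over the 3833 pairs first tested, over pairs that share genes and so are not independent). The 8 genes with both probes bright and at 2-fold or more, chosen after their values were seen, were Ntrk2, Nup93, Syngr1, Lrrfip1, Araf, Ahnak, Aak1 and a clone-named gene, and in Ntrk2, which encodes the neurotrophin receptor TrkB, 1 probe was at -4.07, another, matched to a different transcript, at 2.78, and another, matched to the same transcript as the first, at 1.58.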
